A study of Mus musculus with 6 samples.

How the data were processed

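RNA was measured by sequencing in 6 samples of mouse colon, 3 with DSS-induced chronic colitis and 3 controls. Per the labels' protocols, total RNA was extracted with TRIZOL, and a poly(A) isolation module and a non-directional second-strand module are named, so strand was taken as not recorded and reads of overlapping or antisense genes as shared between them. The deposited values are FPKM (fragments per kilobase of transcript, scaled to mapped fragments) for each gene, per the file headers. TopHat2 2.1.1 and the mm10 build are named in the submitters' processing notes. The program that made the FPKM values and its gene annotation are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. H3K27ac profiles were not analysed here.

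Each sample held 24421 gene rows, of which 5363 were at 0 in every sample. In all, 27 rows carried names that a spreadsheet had turned into dates, and 4 rows shared a name with another. They were kept as separate rows and none is named. Values as low as 1e-06 FPKM and the ratios of low values between samples showed no steps of whole reads (at most 1.86% of genes in a bin of 0.02 log2 units), so depth is unknown and no interval or floor is given. Gapdh, a gene every cell uses, was listed at 0 FPKM in DSS 1, so a 0 can be a failed estimate, and genes at 0 in a whole group are given per sample without a fold. No sample held values identical to those of another.

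The design fixed before the data were examined named a count test for counts and limma for FPKM, and because the files held FPKM the limma form was used. Genes with at least 1 FPKM in at least 3 samples were tested, 12348 in all. Values were taken as log2(FPKM + 1) with no further scaling and fitted on group with limma 3.58.1 in R 4.3.3 (trend and robust moderation), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A total of 44 gene lists were fixed before the data were examined, and the 38 with at least 5 tested members entered camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over lists. Smooth muscle, adipocyte, posterior Hox and some other lists were control lists, for other cell types or technical signs in a piece of colon.

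Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among called genes with groups apart, at least 2 FPKM in the higher group and no predicted or receptor-segment name. It also took up to 4 members of each described list with the smallest p, any member that a count of 5 or fewer rests on, 20 genes fixed in advance, Xist, Ddx3y and the most abundant gene of each sample. Not every gene that met the rule is described. Hoxb13, Acta2 and the genes singled out in the closing section were chosen after their values were seen.

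Coordinates are from GENCODE vM21 on GRCm38, the assembly that mm10 names. Near-identical copies were sought with BLAST+ 2.17.0 among its transcripts, at 95% identity or more over at least 200 bases, leaving out overlapping genes. Of 12328 uniquely named tested genes 12264 were matched and 1433 had such a copy, and values of these are uncertain. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The fit was tested on simulated data for the DSS and control comparison with 12348 genes, 200 of them changed, in 10 sets. It recovered 42.1% of 2-fold and 83.2% of 4-fold changes, and 4.42% of calls were false. Noise was drawn independently for each gene, and the changed genes were not taken from the lowest in control colon. These shares therefore need not hold for the real data, where genes vary together. Alternatives covered other scalings, filters, pseudocounts, moderation, the replicate number as a block, each sample left out, and the set tests.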

Results

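RNA from mouse colon was sequenced in 2 groups of 3 samples. One group had chronic colitis induced with dextran sulfate sodium (DSS), a sulfated polysaccharide that injures the colonic epithelium when given in drinking water, and the other was control colon. All 6 samples were labelled as C57BL/6 mice and as 7 weeks of age. The question behind the comparison, as the series states it, was whether acetylation of histone H3 at lysine 27 takes part in intestinal inflammation. Only expression was analysed here. Each sample was deposited as FPKM values for 24421 gene rows. Read totals are unknown, because the values did not fall into steps of single reads. The FPKM values summed to between 609544 and 678076 per sample, and between 11849 and 12543 genes reached 1 FPKM. The number of genes at 1 FPKM or more was 12330 ± 290 in DSS and 11940 ± 78.9 in control colon (SD, n = 3 each, exact permutation test, two-sided p = 0.1, the smallest p this design allows). Values after ± are SDs over 3 samples unless named SE. No label says whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

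Control samples resembled each other more closely than DSS samples did. Over the 12348 tested genes, Pearson correlations of log2(FPKM + 1) lay between 0.971 and 0.986 within control colon and between 0.936 and 0.961 within DSS colon. Between the groups they lay between 0.892 and 0.937. The first principal component held 59% of the variance and separated the groups, and the second held 17.3% and set DSS 1 apart from DSS 2. On the first component DSS 1 also lay nearer the controls, at a score of 18.98 against 51.17 in DSS 2 and 47.53 in DSS 3. It correlated with DSS 2 at 0.9355 and with the controls at 0.9355, 0.9315 and 0.9367. Lypd8, an anti-flagellin surface protein of colonic epithelium, was the most abundant gene in DSS 1 and in the 3 control samples, at 15464 ± 5960.0 FPKM in DSS and 19149 ± 1074 FPKM in control colon. Reg3b, an antimicrobial lectin, was the most abundant gene in DSS 2 and DSS 3. The Y-linked gene Ddx3y was read in every sample, at 13.5 ± 1.26 FPKM in DSS and 9.25 ± 1.25 FPKM in control colon, and Xist was listed at 0.00380 FPKM in DSS 1 and at 0 in the other samples. Reg3b (0.115) lost the call without DSS 2, DSS 3 or any control and in 1 other setting, with the highest adjusted p over all alternatives in parentheses here and below. A fit without 1 sample held 5 samples, so a call lost in it need not point to the sample left out.

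Genes of neutrophils and of antimicrobial defence were among those with the largest log2 fold changes between DSS and control colon. S100a8 and S100a9, which encode the subunits of calprotectin, rose from 9.25 ± 5.69 to 3229 ± 851 FPKM and from 6.39 ± 4.96 to 2449 ± 721 FPKM. The acute-phase gene Saa3 rose from 5.64 ± 3.67 to 1149.7 ± 377 FPKM. Mptx1, a mucosal pentraxin, fell from 10903 ± 2723 to 26.8 ± 15.8 FPKM, and Ang4, an antimicrobial ribonuclease of secretory epithelial cells, fell from 659.5 ± 412 to 6.68 ± 4.17 FPKM. In total 783 genes were higher and 316 lower in DSS among 12348 tested (limma, Benjamini-Hochberg adjusted p under 0.05).

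The 10 largest rises were S100a9 (log2 fold change 8.56 ± 0.52 SE, adjusted p = 0.000526), S100a8 (log2 fold change 8.42 ± 0.43 SE, adjusted p = 0.000217), Saa3 (log2 fold change 7.58 ± 0.50 SE, adjusted p = 0.000557), Reg3b, Retnlg, Reg3g, Il1b, Chil3, Wfdc21 and Cxcl2. S100a8 lies on chromosome 3, 90668978 to 90670035, and S100a9 on chromosome 3, 90692632 to 90695721, in GRCm38. Reg3b stood at 523, 20719 and 9447 FPKM in DSS 1, 2 and 3 and at 30.03 ± 23.99 FPKM in control colon (log2 fold change 7.50 ± 1.38 SE, adjusted p = 0.0267). Its relative Reg3g stood at 93.9, 1089 and 839 FPKM in the same DSS samples and at 4.29 ± 3.26 FPKM in control colon. Retnlg, a resistin-like gene of neutrophils, had 210.4 ± 21.3 FPKM in DSS and 1.13 ± 0.890 FPKM in control colon (log2 fold change 6.71 ± 0.28 SE, adjusted p = 0.000102). The cytokine gene Il1b had 249 ± 111 FPKM in DSS and 2.75 ± 1.41 FPKM in control colon, and Cxcl2, a neutrophil attractant, had 113 ± 73.8 FPKM in DSS and 0.590 ± 0.425 FPKM in control colon. Chil3, a chitinase-like gene of myeloid cells, had 90.3 ± 42.1 FPKM in DSS and 0.422 ± 0.349 FPKM in control colon, and Wfdc21 had 74.7 ± 16.9 FPKM in DSS and 0.301 ± 0.522 FPKM in control colon. Reg3g (0.0773) lost the call without control 2 or control 3 and in 1 other setting.

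The 10 largest falls were Mptx1 (log2 fold change -8.80 ± 0.50 SE, adjusted p = 0.000393), Ang4 (log2 fold change -6.44 ± 0.58 SE, adjusted p = 0.00187), Tgm3, Slc37a2, Retnla, Mptx2, Eno3, Sycn, Slc15a1 and Klk1b11. Mptx1 lies on chromosome 1, 174330518 to 174332873 in GRCm38, and Ang4 on chromosome 14, 51763878 to 51773590. The transglutaminase gene Tgm3 had 76.01, 0.688 and 2.81 FPKM in DSS 1, 2 and 3 and 534 ± 81.5 FPKM in control colon. Slc37a2, a sugar phosphate exchanger, had 3.16 ± 2.62 FPKM in DSS and 119 ± 22.8 FPKM in control colon. The resistin-like gene Retnla had 0.183 ± 0.318 FPKM in DSS and 31.9 ± 3.15 FPKM in control colon (adjusted p = 0.000102). Eno3, the muscle form of enolase, had 55.2, 4.06 and 9.09 FPKM in DSS 1, 2 and 3 and 293 ± 9.15 FPKM in control colon. Sycn, which encodes syncollin of secretory granules, had 246 ± 161 FPKM in DSS and 3309 ± 398 FPKM in control colon. Slc15a1, the peptide transporter of the intestinal brush border, had 12.8, 1.21 and 1.85 FPKM in DSS 1, 2 and 3 and 66.7 ± 3.24 FPKM in control colon. Mptx2 and Klk1b11 were listed at 0 in the 3 DSS samples and had 16.8, 18.1 and 47.6 FPKM and 9.20, 18.97 and 14.2 FPKM in the control samples. Eno3 (0.11) and Slc15a1 (0.0773) lost their calls without DSS 3 or any control. Tgm3 (0.156) lost the call without DSS 2, DSS 3 or any control and in 4 other settings.

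**Figure D1:**
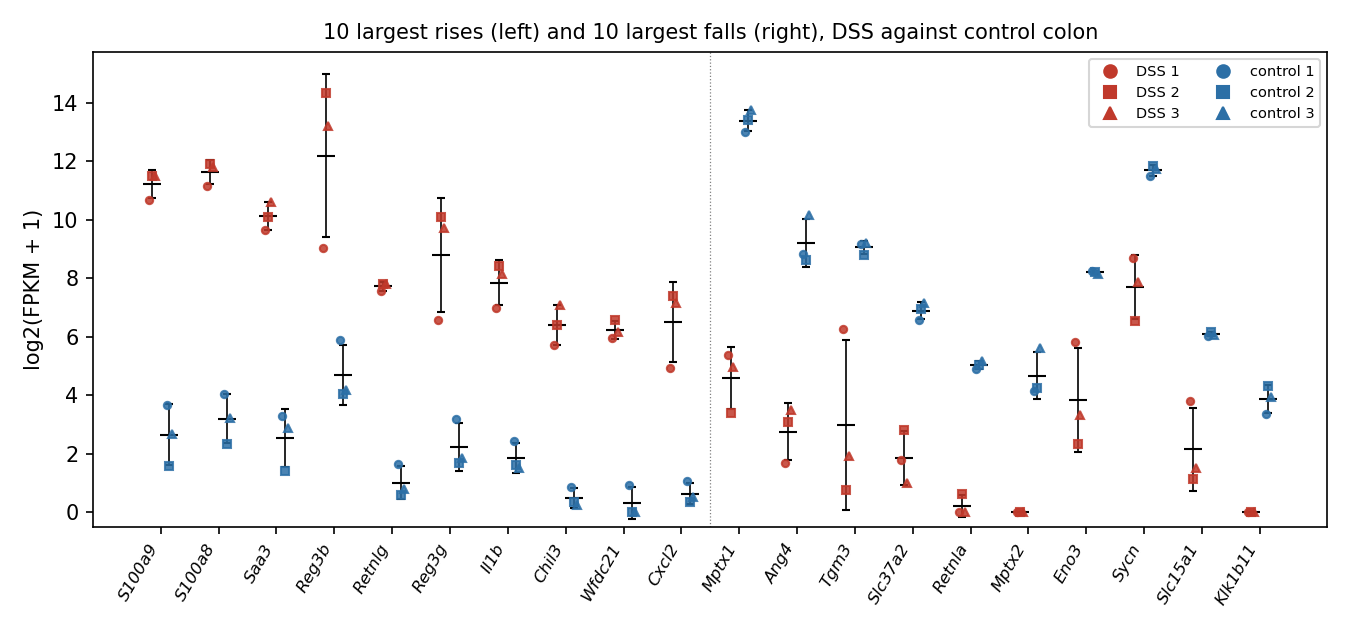
The vertical axis gives log2(FPKM + 1) for each of the 10 genes with the largest rise and the 10 with the largest fall, with 1 point per sample, red for DSS and blue for control. Horizontal marks are group means and bars are SDs over 3 samples, and no DSS point overlaps the control points of its gene.

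Genes of neutrophils and of inflammatory signals rose, in most lists in part. All 11 tested neutrophil markers rose, among them Retnlg, Fpr2 at 4.94 ± 0.309 FPKM in DSS and 0.0847 ± 0.147 FPKM in control colon and Hdc, the histamine-forming decarboxylase, at 7.63 ± 1.48 FPKM in DSS and 0.317 ± 0.108 FPKM in control colon. Stfa2l1, a stefin protease inhibitor, was listed at 0 in control colon and had 23.9, 46.6 and 34.6 FPKM in the DSS samples. Of the tested neutrophil markers 4 have near-identical copies, Fpr2 and Stfa2l1 among them, so their values are uncertain. The neutrophil list stood above other genes (camera, adjusted p = 1.84e-13 with a preset correlation, adjusted p = 0.0972 with an estimated correlation). Of 14 tested cytokine genes 10 rose. Il6 had 9.91 ± 1.32 FPKM in DSS and 0.153 ± 0.133 FPKM in control colon (adjusted p = 0.000217) and Tnf had 7.47 ± 2.40 FPKM in DSS and 0.601 ± 0.253 FPKM in control colon (adjusted p = 0.00236). Ifng and Csf3 were listed at 0 in the control samples, and had 2.89, 3.02 and 3.36 FPKM and 11.9, 8.56 and 7.99 FPKM in the DSS samples. Il17a did not reach the level needed for testing, with 0.687, 0.318 and 3.36 FPKM in the DSS samples and a listed 0 in the control samples. The cytokine list had adjusted p = 1.1e-05 with the preset correlation and adjusted p = 0.0972 with an estimated correlation. Of 26 chemokine genes 14 rose, with Cxcl9 at 18.6 ± 6.98 FPKM in DSS and 0.586 ± 0.0440 FPKM in control colon, Cxcl10 at 40.9 ± 19.7 FPKM in DSS and 4.13 ± 1.20 FPKM in control colon and Ccl5 at 77.9 ± 52.5 FPKM in DSS and 2.87 ± 1.46 FPKM in control colon (adjusted p = 7.83e-05, and adjusted p = 0.0972 with an estimated correlation). Of 20 antimicrobial and acute-phase genes 13 rose and Ang4 fell, and Lcn2, which encodes an iron-siderophore binding protein, had 202 ± 115 FPKM in DSS and 6.93 ± 2.23 FPKM in control colon (adjusted p = 5.31e-06 for the list, and adjusted p = 0.273 with an estimated correlation). Adjusted over the list alone, the counts were 11 higher and 0 lower for neutrophil markers, 10 higher and 1 lower for cytokines, 15 higher and 1 lower for chemokines and 14 higher and 2 lower for antimicrobial genes. Ccl5 (0.0567) lost the call without control 1 or control 2.

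Interferon-stimulated genes, complement genes and markers of lymphocytes and macrophages rose in part. Of 26 interferon-stimulated genes 15 rose, among them the GTPase genes Iigp1 at 48.05 ± 4.31 FPKM in DSS and 2.27 ± 0.195 FPKM in control colon and Igtp at 45.7 ± 5.19 FPKM in DSS and 7.88 ± 1.53 FPKM in control colon, and the immunoproteasome gene Psmb9 at 128 ± 21.7 FPKM in DSS and 34.6 ± 4.23 FPKM in control colon (list adjusted p = 1.21e-07, and adjusted p = 0.335 with an estimated correlation). Of 14 complement genes 6 rose, with C3 at 123 ± 27.3 FPKM in DSS and 19.4 ± 8.96 FPKM in control colon and C4b, which has a near-identical copy, at 36.5 ± 6.53 FPKM in DSS and 6.12 ± 0.480 FPKM in control colon (adjusted p = 7.83e-05, and adjusted p = 0.379 with an estimated correlation). Of 10 T cell and NK markers 7 rose, among them Cd3g at 15.5 ± 8.24 FPKM in DSS and 2.21 ± 0.366 FPKM in control colon and Gzma, a cytotoxic granule protease, at 22.04, 117 and 21.5 FPKM in DSS 1, 2 and 3 and 1.04 ± 0.719 FPKM in control colon (adjusted p = 7.83e-05, and adjusted p = 0.273 with an estimated correlation). Of 17 macrophage and monocyte markers 8 rose, with Clec4e at 19.2 ± 6.39 FPKM in DSS and 0.150 ± 0.131 FPKM in control colon and Arg1 at 10.7 ± 3.88 FPKM in DSS and 0.335 ± 0.206 FPKM in control colon (adjusted p = 0.000341, and adjusted p = 0.273 with an estimated correlation). Of 8 adhesion and homing genes 5 rose, with Vcam1 at 22.1 ± 7.17 FPKM in DSS and 5.15 ± 0.438 FPKM in control colon (adjusted p = 7.83e-05, and adjusted p = 0.374 with an estimated correlation). None of 10 B cell and plasma cell markers passed (0 at an unadjusted limma p under 0.05), and their median log2 difference from control was 1.78 in DSS 1, -0.37 in DSS 2 and -1.39 in DSS 3. H2-DMa and H2-DMb1, the latter with a near-identical copy, rose among 9 genes of MHC class II presentation. Cd14, Pycard, Tlr2 and Tlr3 rose among 16 pattern recognition genes, and neither list was called (camera adjusted p = 0.438 and 0.271). None of 5 dendritic cell markers passed (1 at an unadjusted limma p under 0.05, list adjusted p = 0.595). The B cell list was called, lower, without DSS 1 (adjusted p = 0.00314, 0.00314 to 0.964 over all alternatives). Likewise the MHC class II list was called, higher, without DSS 3 (0.0129, 0.0129 to 0.96 over all alternatives). The estimated correlation was 0.89 for the B cell and 0.84 for the MHC class II list, far above the preset 0.01 behind these calls. Pattern recognition genes were called higher with fry (0.0232, 0.0232 to 0.626 over all alternatives), and dendritic cell markers lower without the filter on low values (0.0195) and with the filter at 0.1 FPKM (0.0375, 0.0195 to 0.913 over all alternatives). Adjusted over the list alone, the counts were 15 higher and 0 lower for interferon-stimulated genes, 8 higher and 0 lower for complement, 8 higher and 0 lower for T cell and NK markers, 11 higher and 0 lower for macrophage markers and 8 higher and 0 lower for adhesion genes. Gzma (0.066) lost the call without control 2 or control 3. H2-DMa (0.112) lost the call without DSS 2, DSS 3 or any control and in 3 other settings. Pycard (0.105) and Tlr3 (0.107) lost their calls without DSS 2, DSS 3 or any control and in 4 other settings.

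Metalloproteinase and inhibitor genes rose in part, while most matrix genes did not pass the test. Of 18 metalloproteinase and inhibitor genes 11 rose, among them the neutrophil collagenase gene Mmp8 at 22.3 ± 4.68 FPKM in DSS and 0.0258 ± 0.0226 FPKM in control colon and Mmp3, a stromelysin with a near-identical copy, at 38.3 ± 20.1 FPKM in DSS and 1.95 ± 0.912 FPKM in control colon. Mmp7 was listed at 0 in control colon and had 8.41, 37.2 and 25.05 FPKM in the DSS samples. Mmp13 had 25.3 ± 15.7 FPKM in DSS and 3.07 ± 1.15 FPKM in control colon (adjusted p = 0.0415). The metalloproteinase list had adjusted p = 0.000238, and adjusted p = 0.374 with an estimated correlation. Lox, which cross-links collagen, at 24.1 ± 11.8 FPKM in DSS and 1.74 ± 0.459 FPKM in control colon, and Spp1, which encodes osteopontin, at 19.6 ± 7.64 FPKM in DSS and 0.592 ± 0.537 FPKM in control colon, were the members that rose among 30 genes of extracellular matrix and fibrosis (list adjusted p = 0.513). Col1a1 had 18.8 ± 12.5 FPKM in DSS and 10.6 ± 1.23 FPKM in control colon (adjusted p = 0.543). Without DSS 2 the matrix list was called, higher (adjusted p = 9.68e-05, 9.68e-05 to 0.975 over all alternatives), and Col1a1 passed (0.0366, 0.0366 to 0.964 over all alternatives), and the median log2 difference of the list from control was 0.81 in DSS 1, -0.44 in DSS 2 and 0.94 in DSS 3. Among 14 fibroblast markers Pdpn rose and Cd34 fell (list adjusted p = 0.754), and Egfl7 rose among 14 endothelial markers (list adjusted p = 0.914). Smooth muscle markers, and the adipocyte markers below, were control lists for other cell types in a piece of colon. Whether the tissue sampled differed in these cell types was not tested. Smooth muscle markers lay lower as a list, with a median log2 fold change of -0.9 over 17 genes (camera adjusted p = 1.21e-07, and 0.426 with an estimated correlation). Tpm2 was the member that fell, from 306 ± 24.9 to 132 ± 53.2 FPKM. Acta2, smooth muscle actin, had 349.8 ± 128 FPKM in DSS and 662 ± 100.5 FPKM in control colon (adjusted p = 0.0672). Acta2 passed without DSS 3 (0.0394) and under upper-quartile (0.0411) and median-of-ratios scaling (0.0372, 0.0372 to 0.188 over all alternatives). The smooth muscle list was not called with fry (adjusted p = 0.21), and its median log2 difference from control was -1.08 in DSS 1, -1.5 in DSS 2 and -0.1 in DSS 3. Adjusted over the list alone, the counts were 11 higher and 0 lower for metalloproteinases and 0 higher and 5 lower for smooth muscle. Of 10 adipocyte markers Adipoq, Car3, Cfd and Retn fell and Cidec and Fabp4 rose, with Adipoq, the adiponectin gene, at 0.302 ± 0.286 FPKM in DSS and 5.64 ± 0.589 FPKM in control colon (list adjusted p = 0.0151, and adjusted p = 0.273 with an estimated correlation, the list alone giving 2 higher and 4 lower). The adipocyte list was no longer called without DSS 1 (adjusted p = 0.101) or under median-of-ratios scaling, with adjusted p up to 0.273 over all alternatives. None of 14 enteric neuron and glia markers passed (1 at an unadjusted limma p under 0.05, list adjusted p = 0.636). Cd34 (0.106) and Egfl7 (0.11) lost their calls without DSS 3 or any control and in 1 other setting. Cidec (0.124) lost the call without DSS 2, DSS 3 or any control and in 5 other settings. Fabp4 (0.107) lost the call without DSS 2, DSS 3 or any control and in 1 other setting. Mmp13 (0.141) lost the call without DSS 1, DSS 3 or any control and in 3 other settings. Pdpn (0.156) lost the call without DSS 3 or any control and in 7 other settings. Tpm2 (0.111) lost the call without any control and in 2 other settings.

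Genes of absorptive epithelium and of ion and water transport fell in part. Of 24 colonocyte genes Aqp8, Car4, Cdhr5, Slc26a2 and Slc26a3 fell and Guca2b rose. The water channel gene Aqp8 had 232 ± 42.01 FPKM in DSS and 1502 ± 366 FPKM in control colon (adjusted p = 0.000821), the chloride-bicarbonate exchanger gene Slc26a3 had 180.3 ± 1.93 FPKM in DSS and 715 ± 213 FPKM in control colon (adjusted p = 0.00305), and the carbonic anhydrase gene Car4 had 251 ± 131 FPKM in DSS and 1663 ± 66.6 FPKM in control colon. Car1, a carbonic anhydrase with a near-identical copy, had 1397, 9924 and 5679 FPKM in DSS 1, 2 and 3 and 2983 ± 652 FPKM in control colon (adjusted p = 0.639). The colonocyte list had adjusted p = 0.000635, and adjusted p = 0.321 with an estimated correlation, and its call was lost without DSS 1 (adjusted p = 0.289) and with fry, with adjusted p up to 0.321 over all alternatives. Of 23 ion and water transport genes 6 fell, with Trpm6, a magnesium channel, at 2.17 ± 0.973 FPKM in DSS and 31.6 ± 6.67 FPKM in control colon, and Aqp1 and Scnn1b rose (adjusted p = 0.00236, and adjusted p = 0.235 with an estimated correlation). Cldn12 at 1.28 ± 1.08 FPKM in DSS and 18.5 ± 0.238 FPKM in control colon and Cldn3 at 216 ± 4.79 FPKM in DSS and 377 ± 51.4 FPKM in control colon fell among 20 junction genes (adjusted p = 2.31e-05, and adjusted p = 0.0972 with an estimated correlation). Cldn2, a pore-forming claudin, had 53.2 ± 16.2 FPKM in DSS and 24.6 ± 5.37 FPKM in control colon (adjusted p = 0.0516), and Cldn8 had 39.1 ± 30.2 FPKM in DSS and 73.1 ± 17.9 FPKM in control colon (adjusted p = 0.189). Among 19 goblet cell genes Clca1 at 404 ± 313 FPKM in DSS and 3680.4 ± 353 FPKM in control colon and Capn9 fell and Galnt12 rose (list adjusted p = 0.0879), and the mucin gene Muc2 had 488 ± 344 FPKM in DSS and 186 ± 44.6 FPKM in control colon (adjusted p = 0.177). Without DSS 1, Car1 (0.0211, 0.0211 to 0.96 over all alternatives), Cldn2 (0.0105, 0.0105 to 0.151 over all alternatives) and Muc2 (0.0338, 0.0338 to 0.368 over all alternatives) passed as higher and Cldn8 as lower (0.00456, 0.00456 to 0.416 over all alternatives), and Cldn2 also passed with the replicate number as a block (0.0217). The goblet cell list was called, lower, without DSS 2 (0.017) or DSS 3 (0.0441, 0.017 to 0.746 over all alternatives). Adjusted over the list alone, the counts were 1 higher and 7 lower for colonocyte genes, 3 higher and 8 lower for transport and 1 higher and 7 lower for junctions. Beside these groups, posterior Hox genes, which mark position along the gut, also lay lower as a list of 9, of which Hoxd11 fell (adjusted p = 0.0338, and adjusted p = 0.353 with an estimated correlation). That call was lost without control 3 (adjusted p = 0.0551), without the filter on low values, with fry (adjusted p = 0.273) and under 3 other scalings, with adjusted p up to 0.353. Hoxb13 stood at 183, 0.472 and 16.1 FPKM in DSS 1, 2 and 3 and at 129, 229 and 278 FPKM in the control samples, so that DSS 1 lay in the range of the controls. Aqp1 (0.124) lost the call without DSS 2, DSS 3 or any control and in 6 other settings. Capn9 (0.0715) lost the call without DSS 3, control 1 or control 2. Cdhr5 (0.108) and Galnt12 (0.0947) lost their calls without DSS 2, DSS 3 or any control and in 1 other setting. Clca1 (0.0574) lost the call without any control. Cldn3 (0.0993) lost the call without DSS 3, control 2 or control 3. Guca2b (0.147) lost the call without DSS 2, DSS 3 or any control and in 8 other settings. Hoxd11 (0.0941) lost the call without DSS 3 or any control. Scnn1b (0.13) lost the call without DSS 2, DSS 3 or any control and in 5 other settings.

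**Figure D2:**
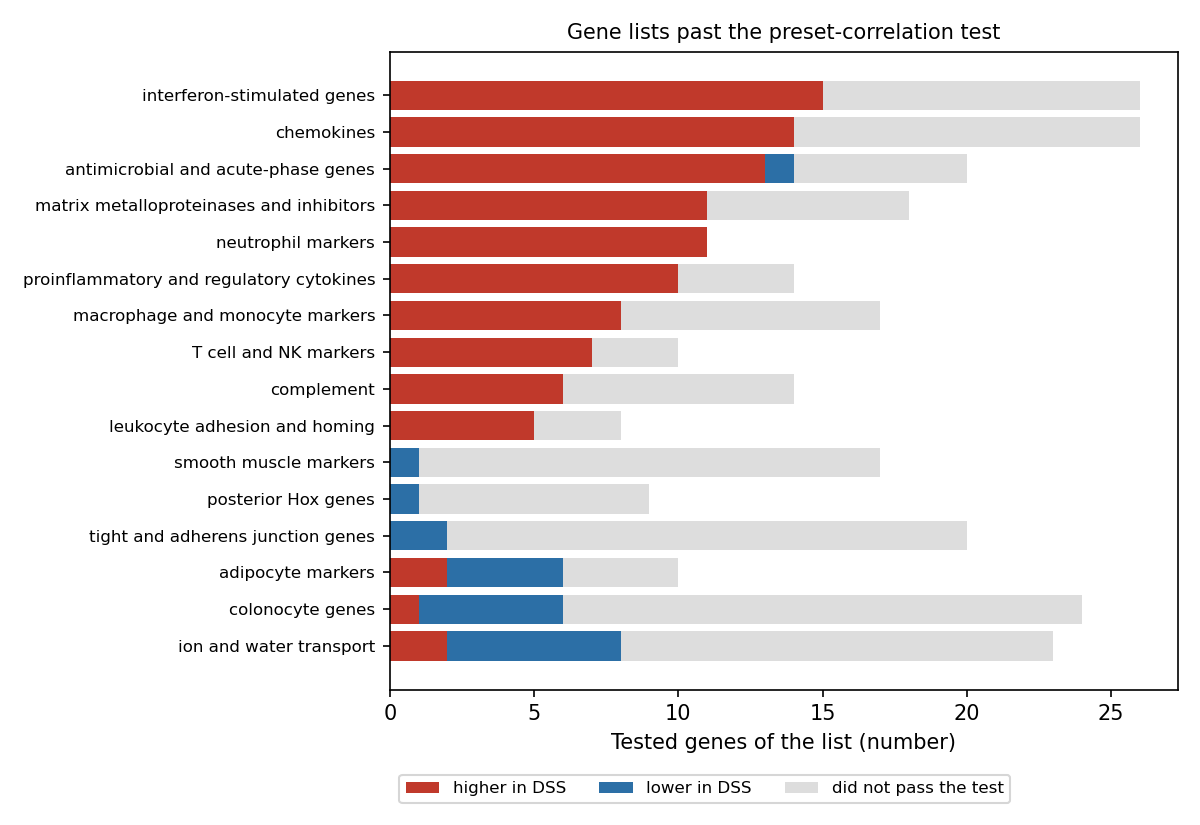
Each bar is 1 of the 16 gene lists past the camera test with a preset correlation, and its length on the horizontal axis is the number of tested genes. The smooth muscle, adipocyte and posterior Hox lists were control lists. Red counts genes that were higher in DSS, blue counts genes that were lower and grey counts genes that did not pass, and all 11 neutrophil markers are red.

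**Figure D3:**
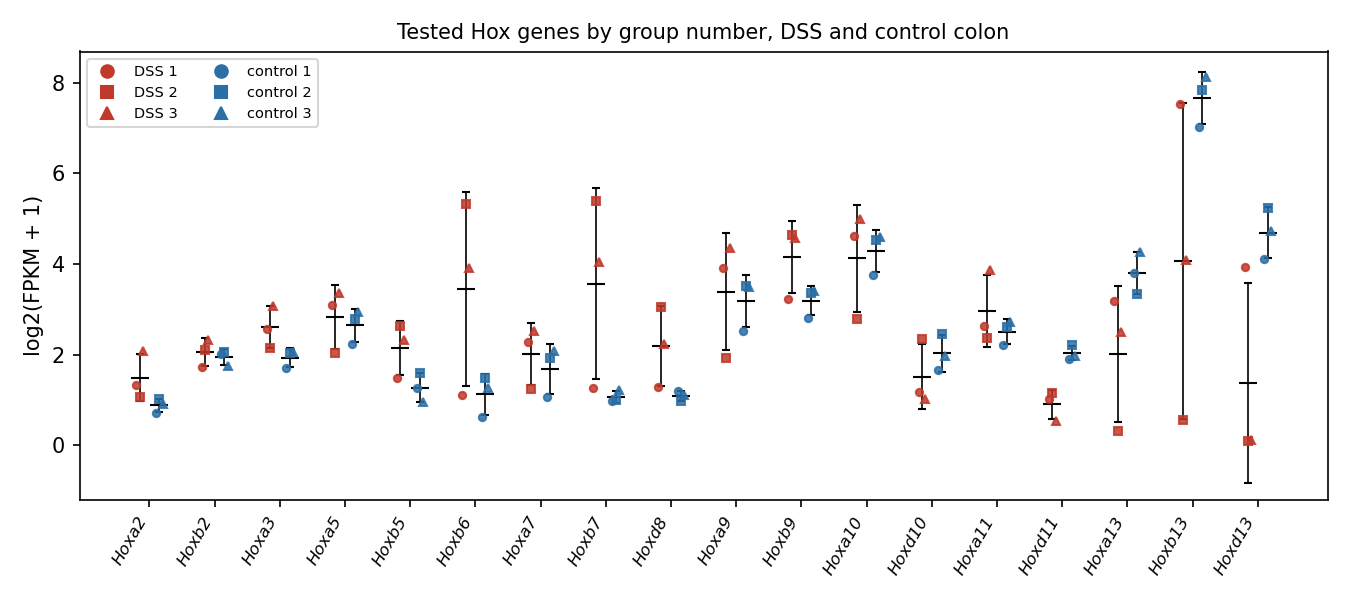
The vertical axis gives log2(FPKM + 1) for the 18 tested Hox genes, ordered from left to right by group number, with 1 point per sample, red for DSS and blue for control, horizontal marks at group means and bars for SDs over 3 samples. Hoxb13 and Hoxd13 at the right lie low in DSS 2 and DSS 3 and near the controls in DSS 1, and Hoxb6 and Hoxb7 lie high in DSS 2 and DSS 3.

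None of 30 genes for histone acetylation writers, erasers and readers passed the test over all genes or over the list alone (5 at an unadjusted limma p under 0.05, list adjusted p = 0.914). Ep300, an acetyltransferase for lysine 27 of histone H3, had 7.18 ± 0.499 FPKM in DSS and 5.17 ± 0.269 FPKM in control colon (adjusted p = 0.128). The deacetylase gene Hdac3 had 37.6 ± 5.18 FPKM in DSS and 25.8 ± 1.98 FPKM in control colon (adjusted p = 0.0787). The list's fry test of change in either direction gave adjusted p = 0.000593, which does not compare it with other genes.

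Other lists were not called by camera with the preset correlation, although single members passed. Rrm2, a ribonucleotide reductase with a near-identical copy, rose among 25 cell cycle genes (list adjusted p = 0.469). Cd44 and Prom1 rose among 13 crypt stem and progenitor genes (0.775). Cd36 and Slc25a20, the latter with a near-identical copy, fell among 23 genes of fatty acid oxidation and ketogenesis (0.748). Gstm1 and Gstm3, glutathione transferases with near-identical copies, fell among 20 xenobiotic genes (0.0748). Uqcrq rose and Sdhb fell among 29 nuclear genes of oxidative phosphorylation (0.604). Bnip3, which has a near-identical copy, and Slc16a3 rose among 22 glycolysis and hypoxia genes (0.204), and 5 tuft cell genes were tested as a list (0.914). Mptx1 and Mptx2 fell among 8 Paneth and small intestine markers (0.0818), of which 3 were higher and 4 lower over the list alone. Of the same list, Alpi had 7.19 ± 5.35 FPKM in DSS and 0.198 ± 0.190 FPKM in control colon. Slc10a2 had 27.6 ± 30.4 FPKM in DSS and 1.72 ± 0.297 FPKM in control colon, and neither was called (limma adjusted p = 0.0669 and 0.0590). None passed among 20 genes of the unfolded protein response (0.694), 14 enteroendocrine genes (0.363) and 13 immediate early and heat shock genes (0.0598), with 2, 5 and 6 at an unadjusted limma p under 0.05. Nr1d1 and Arntl fell and Per2 and Cry1 rose among 15 circadian clock genes (0.932), with Nr1d1 at 5.64 ± 2.32 FPKM in DSS and 29.6 ± 3.11 FPKM in control colon. Calls appeared in some alternatives. The cell cycle list was called lower without DSS 1 (0.0162) and higher without DSS 2 (0.00319, 0.00319 to 0.96 over all alternatives). Its estimated correlation over all samples was 0.9, far above the preset 0.01 behind these calls. Without DSS 2, the fatty acid (0.0409, 0.0409 to 0.992 over all alternatives), xenobiotic (3.83e-05, 3.83e-05 to 0.742 over all alternatives) and Paneth and small intestine lists (0.0125) were called lower. The last of these was also called lower without control 2 (0.0393) and with fry (0.0232, 0.0125 to 0.424 over all alternatives). Immediate early genes were called lower without DSS 2 (0.0125), DSS 3 (0.0129), control 2 (0.0239) or control 3 (0.0164, 0.0125 to 0.672 over all alternatives), and clock genes higher with fry (0.0495, 0.0495 to 0.999 over all alternatives). Too few members were tested for a list test of mast cell and eosinophil, skeletal muscle, squamous, pancreatic acinar, erythrocyte and sex-linked genes. Of these, Krt17 and Cela1 fell and the Y-linked gene Eif2s3y rose, from 30.8 ± 0.493 to 60.8 ± 3.73 FPKM. Camera pointed down where the median was above 0 for fibroblast, cell cycle, fatty acid, oxidative phosphorylation, histone acetylation and enteric neuron genes. Median and mean had different signs for B cell, dendritic cell, xenobiotic and glycolysis genes. Arntl (0.136) lost the call without DSS 2, DSS 3 or any control and in 1 other setting. Bnip3 (0.124) lost the call without DSS 3 or any control and in 2 other settings. Cd36 (0.0643) and Krt17 (0.072) lost their calls without control 1 or control 2. Cd44 (0.0715), Prom1 (0.0851) and Uqcrq (0.0629) lost their calls without DSS 3, control 2 or control 3. Cela1 (0.141) lost the call without DSS 2, DSS 3 or any control and in 2 other settings. Cry1 (0.104) lost the call without DSS 3 or any control and in 4 other settings. Gstm1 (0.0502) and Per2 (0.0518) lost their calls without control 2. Gstm3 (0.13) lost the call without DSS 1, DSS 2 or any control and in 1 other setting. Sdhb (0.118) lost the call without DSS 2, DSS 3, control 2 or control 3 and in 2 other settings. Slc16a3 (0.0998) lost the call without DSS 3 or any control and in 1 other setting. Slc25a20 (0.159) lost the call without DSS 1, DSS 3 or any control and in 3 other settings.

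The number of called genes changed when a single sample was left out. It was 1771 without DSS 1, 939 without DSS 2, 477 without DSS 3, 458 without control 1, 288 without control 2 and 296 without control 3. Each of these fits held 5 samples, so a lower number need not come from the sample left out. The median log2 fold change over all tested genes was 0.134, and the split of 783 higher and 316 lower genes became 529 and 513 under median-of-ratios scaling, which sets that median to 0. The 38 tested lists gave 16 calls with the preset correlation and 0 with an estimated correlation, where camera gave 6 at an unadjusted p under 0.05. The estimated form also gave a far higher p for a raised list in simulated data without correlated genes. Fry gave 16 calls, of which 13 were shared with the preset correlation.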

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

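The median-of-ratios scaling, the removal of genes with near-identical copies and the pseudocount of 0.1 for lists were chosen after the data were seen, and the other alternatives before. DESeq2 size factors, the DESeq2 Wald test and voom were not run, because they need counts. The 1099 called genes became between 788 and 1104 under other scalings, filters, pseudocounts and moderation, 896 without genes that have a near-identical copy, and 685 with an absolute log2 fold change of at least 1, fewer by construction. The higher share of 71.2% became 53.8% under upper-quartile scaling (544 higher, 467 lower), 51.8% under quantile normalization (535 and 497) and 50.8% under median-of-ratios scaling (529 and 513), and for these the cause was not tested. Leaving out 1 sample gave between 288 and 1771 genes, with 5 samples in each fit, and 16 to 23 lists. The 16 called lists became 14 to 17 under other scalings and filters, 16 with fry, 13 of them shared, and 0 with an estimated correlation. The estimate was 0.01 for cytokines, junctions and ion and water transport, -0.02 for chemokines and -0.03 for adipocyte markers. These values lie close to or below the preset 0.01, so a higher correlation does not account for these losses. In simulated data with noise drawn independently for each gene, 1 list of 20 genes was raised by 1 log2 unit. Its camera adjusted p was 3.27e-34 with the preset and 0.0351 with the estimated correlation. The estimated form thus gave a far higher p without correlated genes, and a call lost under it need not speak against a list. In the other called lists the estimate was higher, from 0.06 for neutrophil markers to 0.91 for smooth muscle markers. The replicate block gave 895 genes, 756 of them shared, and 16 lists. Same-numbered samples correlated at 0.082, 0.13 and 0.0031 in their deviations, against a threshold of 0.1 that replicate 2 exceeded. DSS 1 and DSS 2 correlated best with the control of their own number, and DSS 3 correlated best with control 1. With 3 samples in a group this cannot decide whether the numbers pair the samples. The excess of within-group over between-group correlation was 0.0503, and 0.4331 over the 500 most variable genes, which are chosen for differing. Of 118 called genes followed singly none changed direction under any alternative. For every called gene the DSS values lay on one side of all control values. Leaving out a sample, the filter, the pseudocount, the replicate block and the moderation therefore could not turn a direction, and only the scalings could. Calls were lost by 3 without DSS 1, 18 without DSS 2, 38 without DSS 3, 40, 50 and 45 without control 1, 2 and 3, 24 without the filter on low values and 12 with the replicate block. Depth is unknown, so it sets no stated limit on low values.

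Direction turned for lists and genes that had not been called, with adjusted p in parentheses and the cause not tested. It turned without a filter for crypt stem and progenitor genes (0.929), tuft cell genes (0.285), histone acetylation writers and related genes (0.84), with at least 0.1 FPKM in at least 3 samples for crypt stem and progenitor genes (0.77), tuft cell genes (0.389), histone acetylation writers and related genes (0.996), under median-of-ratios scaling for B cell and plasma cell markers (0.961), and under fry, which makes no comparison with other genes, for fibroblast markers (0.907), B cell and plasma cell markers (0.942), cell cycle (0.91), fatty acid oxidation and ketogenesis (0.907), oxidative phosphorylation (0.621), histone acetylation writers and related genes (0.364), enteric neuron and glia markers (0.91). With 1 sample left out, direction turned at least once within these ranges of adjusted p: B cell and plasma cell markers 0.00314 to 0.902, MHC class II presentation 0.0129 to 0.719, cell cycle 0.00319 to 0.695, circadian clock genes 0.714 to 0.998, endothelial markers 0.117 to 0.998, enteric neuron and glia markers 0.226 to 0.881, fatty acid oxidation and ketogenesis 0.0409 to 0.992, fibroblast markers 0.263 to 0.94, histone acetylation writers and related genes 0.727 to 0.975, tuft cell genes 0.672 to 0.998, unfolded protein response 0.205 to 0.998, xenobiotic metabolism 3.83e-05 to 0.672. In the turned direction the cell cycle list passed, higher without DSS 2, and it passed as lower without DSS 1. In their first direction the B cell list passed without DSS 1, the MHC class II list without DSS 3, and the fatty acid and xenobiotic lists without DSS 2. The log2 fold change of Car1 lay between -0.06 and 1.35 with 1 sample left out.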

Other observations

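The genes singled out in the first 2 paragraphs, and the tests of Hox group number, general epithelial genes, near-identical copies and clock peak times, were chosen only after the values had been seen. Forms of the Hox tests that set DSS 2 and DSS 3 against the controls, and a comparison of DSS 1 with the controls, were also run and left out, because those samples had been picked by their values. Retnlb, a goblet cell product, rose from 124 ± 82.2 to 3337 ± 2492 FPKM (limma adjusted p = 0.0362), as did Retnlg, while Retnla fell. The Retnlb call was lost without DSS 2, DSS 3 or any control sample and without the filter on low values, with adjusted p up to 0.118 over all alternatives. No list of stefin or gasdermin genes was fixed or tested. Stfa1 rose, with 35.8 ± 15.4 FPKM in DSS and 0.249 ± 0.132 FPKM in control colon, and Stfa2 and Stfa3 were listed at 0 in the control samples, which can be a failed estimate, and had 16.3, 33.2 and 45.5 FPKM and 9.62, 16.8 and 24.8 FPKM in the DSS samples. Stfa1 and Stfa2 have near-identical copies. Gsdmc4 fell from 699 ± 28.7 to 134 ± 96.5 FPKM, Gsdmc3 from 84.6 ± 5.66 to 20.2 ± 6.56 FPKM and Gsdmc from 12.6 ± 0.990 to 3.14 ± 1.09 FPKM, and Gsdmc2 had 64.1 ± 25.7 FPKM in DSS and 141 ± 33.1 FPKM in control colon (adjusted p = 0.0735). Gsdmc2 and Gsdmc3 have near-identical copies, and the call of Gsdmc4 was lost without DSS 2 or any control sample, with adjusted p up to 0.0931.

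Pancreatic enzyme genes were read in DSS 1. Ctrb1 had 15.3 FPKM, Amy2a2 10.2 FPKM and Cela2a 9.32 FPKM there. Amy2a2 and Cela2a were listed at 0 in the other 5 samples, and Ctrb1 reached at most 0.107 FPKM in them, in DSS 2.

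Of the 10 splits of the 6 samples into 3 and 3, 1 gave as many genes as the real split, which was the real split itself, with 1099 genes against at most 2 in the others. So few splits cannot give a share under 0.05.

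Posterior Hox genes lay lower in DSS colon as a list, a call that was lost without control 3 (adjusted p = 0.0551) and under other settings, and Hoxd13 stood at 14.2, 0.0586 and 0.0866 FPKM in DSS 1, 2 and 3 and at 26.2 ± 10.3 FPKM in control colon. Hoxb6, a more anterior gene, stood at 1.17, 39.2 and 13.97 FPKM and 1.24 ± 0.637 FPKM, and neither gene was called, although both were without DSS 1 (adjusted p = 0.000267, 0.000267 to 0.257 over all alternatives, and 0.0046, 0.0046 to 0.374 over all alternatives). Loss of epithelium cannot be told apart from the other explanations, because the median log2 fold change of 12 general epithelial genes was -0.41 ± 0.75 (SD over genes), against a median of -0.52 and a mean of -0.99 for the list, whose median difference from control was -0.14 in DSS 1, -1.27 in DSS 2 and -1.01 in DSS 3. Tissue taken further from the rectum cannot be told apart from them either, because the fall of the log2 fold change with the Hox group number over 18 genes (Spearman rho = -0.61) largely restates that the posterior genes lay lower. An effect of colitis itself stays open and untested. Whether the position of the tissue also bears on other differences between DSS and control colon was not tested.

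Some genes were near 0 in 1 control sample and abundant in another. Of 6 genes under 1 FPKM in 1 control and at 20 FPKM or more in another, 5 had a near-identical copy (83.3%), against 16.7% of 3945 other genes (Fisher's exact test, two-sided, p = 0.000674). Atp6v0c had 0.976, 2.51 and 156 FPKM in control 1, 2 and 3, where its pseudogene Atp6v0c-ps2, also among the 5, had 162, 152 and 0.058 FPKM. Reads shared between copies are thus a candidate explanation for these 5 genes and not for Neat1, which had no such copy. No biological explanation was tested.

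Of 15 clock genes Nr1d1 and Arntl fell, Cry1 and Per2 rose, 11 did not pass, and the list was not called (camera adjusted p = 0.932). Camera looks for a shift in a common direction, so it cannot speak to members that moved in opposite directions. Over the list alone 6 were higher and 3 lower, and 9 had an unadjusted limma p under 0.05. The list's fry test of change in either direction gave adjusted p = 0.00161, which does not compare it with other genes. Per2 had 5.65 ± 1.03 FPKM in DSS and 1.54 ± 0.439 FPKM in control colon, although the call of Per2 was lost without control 2, that of Arntl on leaving out any sample except DSS 1 and without the filter on low values, and that of Cry1 in 8 settings (adjusted p up to 0.0518, 0.136 and 0.104 over all alternatives). A cosine of textbook peak times explained 61.3% of the log2 fold changes over 15 clock genes, against a median of 11.1% for permuted peak times (permutation p = 0.0025, across genes, which are not independent replicates). A different time of day at collection, which no label gives, would give such a fit. The test was chosen after the values of these genes had been seen, so the fit partly restates their opposed shifts and decides nothing. An effect of colitis on the clock stays open and untested.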
